A study of Homo sapiens with 12 samples.

How the data were processed

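The data were 12 Affymetrix arrays of 54675 probe sets, 3 each for MMS1 with a control sponge, MMS1 with a miR-16 sponge, RPMI8226 with a control sponge and RPMI8226 with a miR-16 sponge. Groups were read from the labels, where the sponge groups carry the abbreviation miR16 KO and the line RPMI8226 is RPMI in the sample titles and RPMI826 in other labels. Per the labels' protocols, cells were transduced, sorted and expanded, grown in parallel flasks and lysed at the same time, and RNA was purified on RNeasy columns. Per the labels' protocols, 15 µg of total RNA went through 2 rounds of linear amplification and were labelled with biotin. The deposited values are log2 signals, 1 per probe set and array, and ran from 4.00 to 14.71 over the probe sets tested. They have a lower bound of 4, which is 16 on the linear scale. The method by which the authors summarized probes and scaled arrays is not given in the sources used here. The array medians lay between 5.80 and 5.90, so no further normalization was applied. Detection flags and scan dates were not used here.

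After 62 Affymetrix control probe sets were left out, 54613 were tested. Of the probe sets, 41097 named 1 gene, 1801 named several and 11777 named none. Gene symbols were matched by identifier to a gene table of the assembly GRCh38.p14. For 54 identifiers with no match the older symbol was kept. Each of 19775 genes was represented by the probe set, among those naming that gene alone, with the highest mean over the 12 arrays. The gene table served only for names and for which genes neighbour each other. No coordinates are printed, because the array's own annotation names no build.

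A linear model with 1 mean per group was fitted to all 12 arrays in limma 3.58.1 under R 4.3.3, with 8 residual degrees of freedom, a prior of 4.92 degrees of freedom and a prior variance of 0.0273. From it came the sponge effect in MMS1, the sponge effect in RPMI8226, their average, their difference (RPMI8226 effect minus MMS1 effect) and the difference between the control-sponge arrays of the lines. All p-values for single probe sets are two-sided, from limma's moderated test with Benjamini-Hochberg adjustment within each comparison, and a call means an adjusted p under 0.05. Counts and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The overlap of called genes between lines was compared with the product of the marginal counts and by two-sided Fisher's exact tests.

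Gene lists, 29 in number, were written before the data were examined, as were the comparisons, the thresholds, the alternatives and the rule for naming genes. Their tests used limma's camera with a preset correlation of 0.01 between genes, adjusted over the 29 lists, and members were also counted with p-values adjusted over the list alone. Camera with an estimated correlation called 0 lists in any comparison. Limma's fry test, which asks whether the members of a list move on balance one way and does not compare them with other genes, called 14 lists in MMS1, 7 in RPMI8226, 15 in the average and 14 in the difference. Lists of erythroid, immunoglobulin and megakaryocyte genes were added after the data had been seen and were adjusted among themselves. Of 13 immunoglobulin genes 3 rose in MMS1, or 4 adjusted over the list alone (camera, adjusted p = 0.00977, and 0.164 with an estimated correlation), and 0 passed in RPMI8226 (adjusted p = 0.267). Of 9 megakaryocyte genes 0 passed in either line (adjusted p = 0.544 and 0.451). To place the lists by signal, the median percentile of their members was compared with 10000 random lists of the same size.

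The rule named, for each line, up to 8 genes each way with the largest change among called genes whose 3 sponge arrays lay all on 1 side of the 3 control arrays. It named 6 genes each way for the average, with the same direction in both lines, and 5 each way for the difference. From each list described it named up to 4 members with the smallest p. From the published target list it named every member called in either line, and BCL2, CCND1, CCND2, CCND3, CCNE1, CDK6, VEGFA and MCL1, with the host genes DLEU2 and SMC4. Genes outside the rule, such as erythroid genes, HBB and HBD in MMS1, CD24 and CXCL8, were chosen after their values had been seen. Some genes were skipped by the rule and are not reported here.

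The fit was tested on simulated data of 54613 probe sets with the spread of these arrays, in which 200 were changed. For the MMS1 comparison, 20.9% of changes of 0.5 on the log2 scale, 83.6% of changes of 1 and 100% of changes of 2 were called. For the RPMI8226 comparison the shares were 22.4%, 79.1% and 100%. Of 54413 unchanged probe sets, 6 and 5 were called. In the real MMS1 comparison 5635 probe sets were called, so its cutoff was looser than in the simulation. The simulated shares therefore do not describe the MMS1 test.

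Replicate numbers were checked for pairing. Residuals of arrays with the same number in different groups of a line correlated across probe sets between -0.075 and 0.027, and those with different numbers between -0.064 and 0.093, so the numbers were not used as pairs. Pearson correlations between arrays ran from 0.974 to 0.986 within groups and from 0.951 to 0.984 between groups, with 0.960 to 0.969 between the groups of MMS1 and 0.974 to 0.984 between those of RPMI8226, and no columns were identical. MMS1 miR-16 sponge replicate 1 had 28S ribosomal RNA signal of 7.99 against 8.75 to 9.53, an actin 3′ minus 5′ difference of 0.485 against 0.082 to 0.342, and an array weight of 0.377 against 0.747 to 1.46. It was kept. Counts of calls, shared genes, the single-gene results and the lists called in each line and in the average were also computed without it.

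Alternatives were replicate number as a block, quantile normalization, median centring, a variance trend with and without robust estimation, the upper 50 percent of probe sets by mean signal, array weights, each line alone, a log2 change of at least 1, an adjusted p under 0.01, the mean over all probe sets of a gene, and leaving out each array in turn. Alternative pseudocounts did not apply to values already on the log2 scale. A search for miR-16 seed sites in 3′ untranslated regions was not run, since transcript sequences were not used here.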

Results

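Transcript levels were measured on 12 Affymetrix expression arrays, in 4 groups of 3. The arrays were labelled as 2 multiple myeloma cell lines, MMS1 and RPMI8226, the second given as RPMI or RPMI826 in part of the labels. Per the labels, the cells had been transduced with lentiviruses carrying GFP and either a sponge that binds the microRNA miR-16 or a control mock sponge, sorted by flow cytometry and expanded. A sponge is a transcript with many copies of a microRNA binding site, which takes the microRNA away from its targets. The stated purpose was to mimic the loss of miR-16 that comes with deletion of 13q and to look for its target genes. The number of arrays limits the precision: the median standard error of a log2 difference between 2 groups of 3 arrays was 0.14. Per the labels, the cells grew in parallel flasks, but the labels do not tie each array to its own flask. The p-values therefore measure only the spread between these arrays. All adjusted p-values for single genes come from limma's moderated test with Benjamini-Hochberg adjustment over 54613 probe sets. Among the 12 arrays, MMS1 miR-16 sponge replicate 1 stood apart in its control probes. Its mean 18S ribosomal RNA signal was 7.84 on the log2 scale, against 9.56 to 11.1 on the other arrays.

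Genes of the plasma cell, the cell type of multiple myeloma, did not stand above other genes on any of the 12 arrays, while genes of red cell precursors did. The embryonic globin gene HBE1 had a mean log2 signal of 14.16 ± 0.23 (SD, n = 12 arrays) and HBZ of 13.06 ± 0.72. The erythroid transcription factor genes GATA1 and KLF1 stood at 9.56 ± 0.20 and 9.27 ± 0.79. The plasma cell genes TNFRSF17, which encodes the receptor BCMA, and JCHAIN, which encodes the joining chain of antibodies, stood at 4.46 ± 0.26 and 4.20 ± 0.24, near the lower bound of 4. CD38, a surface marker of plasma cells, stood at 4.91 ± 0.32, and IRF4, a transcription factor on which myeloma cells depend, at 6.47 ± 0.15. The immunoglobulin light chain genes IGKC (kappa) and IGLC1 (lambda) stood at 6.46 and 5.70. The median gene stood at 6.44 and the upper quartile at 7.62. Of 20 plasma cell genes, 3 lay above the upper quartile, namely SDC1 at 8.90 ± 0.22, XBP1 at 8.51 ± 0.16 and SSR4 at 10.30 ± 0.11, and 10 lay below the median gene. Of 13 immunoglobulin genes, 0 lay above the upper quartile. Of 24 erythroid genes, 14 lay above it and 6 below the median gene, among them AHSP at 5.53 and SLC4A1 at 5.99. On single arrays the median plasma cell gene lay at percentile 41.5 to 47.6 of all genes, the median immunoglobulin gene at 42.8 to 54.9 and the median erythroid gene at 69.8 to 85.5. Of 10000 random lists of the same size, 69.4% had a higher median than the plasma cell list, 49.4% a higher median than the immunoglobulin list and 0.02% a higher median than the erythroid list. The median ribosomal protein gene lay at percentile 99.8. Such percentiles also depend on how strongly each probe set binds its transcript. The erythroid and immunoglobulin lists were chosen after signals of these genes had been seen.

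**Figure D1:**
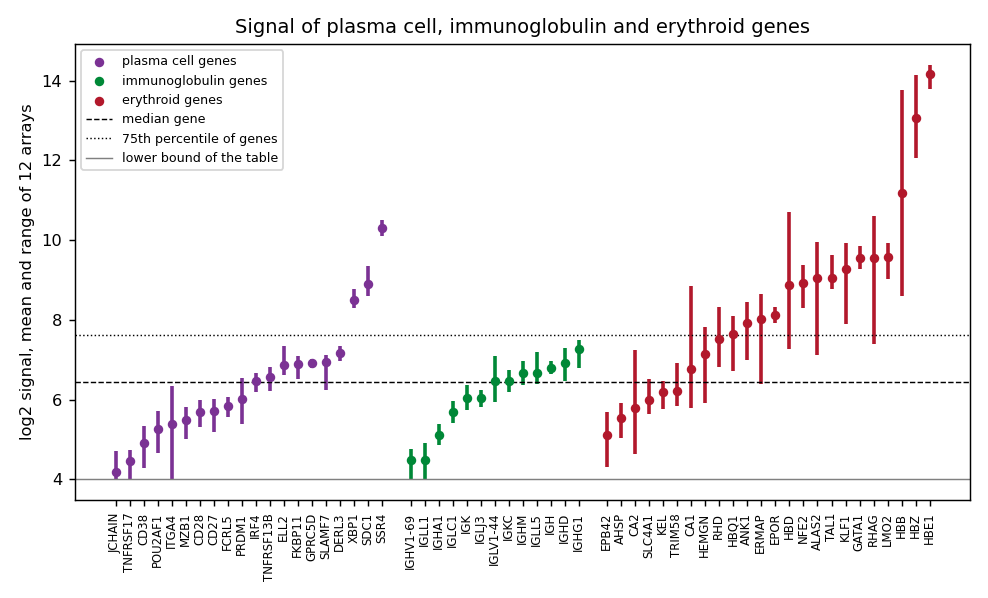
Mean log2 signal over the 12 arrays (points) and range from the lowest to the highest array (lines) for plasma cell, immunoglobulin and erythroid genes, 1 gene per position. HBE1 stood at 14.16 and JCHAIN at 4.20, against a median gene at 6.44.

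The first question was whether genes known as miR-16 targets rose when the sponge was present. MiR-16 itself was not measured by these probe sets. Its host genes, whose transcripts carry the microRNA in introns, were measured, but their levels say nothing on whether a sponge worked. DLEU2 gave a log2 change of -0.23 in MMS1 (adjusted p = 0.291) and -0.27 in RPMI8226 (adjusted p = 0.344). SMC4 gave 0.37 (adjusted p = 0.0701) and -0.23 (adjusted p = 0.434); the MMS1 value passed without MMS1 control sponge replicate 3 (adjusted p = 0.0364) with quantile normalization (adjusted p = 0.0274) and among the brighter probe sets (adjusted p = 0.0227). Among 39 measured published targets, 2 rose and 7 fell in MMS1. Adjusted over the list alone, 3 rose and 9 fell. JUN, a subunit of the transcription factor AP-1, rose from 7.52 ± 0.10 to 8.54 ± 0.10 (SD, n = 3 each), a log2 change of 1.02 (adjusted p = 3.36e-05). VEGFA, a growth factor for blood vessels, rose by 0.52 (adjusted p = 0.0107). The transcription factor gene ETS1 fell by 1.35 (adjusted p = 4.86e-06) and the kinase gene IKBKB fell by 1.30 (adjusted p = 0.00281). PURA fell by 0.69, CDK6 fell by 0.55, CCND2 fell by 0.46, UNG fell by 0.42 and HMGA1 fell by 0.39. In RPMI8226, 0 of the 39 passed limma's test over all probe sets, and 0 rose and 5 fell adjusted over the list alone. At an unadjusted p under 0.05, 7459 of all probe sets passed in that line. Without MMS1 miR-16 sponge replicate 1, CDC27 and UNG passed as lower in RPMI8226 (adjusted p = 0.0478 and 0.0463). Among the brighter probe sets CDC27, UNG and PIM1 did (adjusted p = 0.0231, 0.0269 and 0.0335).

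BCL2, which encodes an inhibitor of cell death and is the best known target, gave -0.14 in MMS1 (adjusted p = 0.476) and 0.04 in RPMI8226 (adjusted p = 0.902). The cyclin genes gave -0.05 and -0.02 for CCND1, -0.27 and 0.03 for CCND3, and -0.03 and 0.00 for CCNE1. MCL1, another inhibitor of cell death, gave -0.14 and -0.11. None of these 5 passed in either line. The median change of the target list was -0.05 in MMS1 (camera, adjusted p = 0.625) and -0.09 in RPMI8226 (adjusted p = 0.0673). With an estimated correlation these were 0.887 and 0.614. In the average of both lines, 2 targets rose and 8 fell, with a median of -0.10 (camera, adjusted p = 0.21). That list value was 0.711 with an estimated correlation and 0.0491 with fry. Without MMS1 miR-16 sponge replicate 1, the list passed as lower in RPMI8226 (adjusted p = 0.0372) and in the average of both lines (adjusted p = 0.0357). With the mean over all probe sets of a gene, the RPMI8226 value was 0.0245. Several of the single falls were fragile. CCND2 lost its call in MMS1 without any of 4 arrays (adjusted p = 0.06 to 0.0782) and UNG without any of the same 4 (adjusted p = 0.0587 to 0.0977), namely MMS1 control sponge replicates 1 and 3 and MMS1 miR-16 sponge replicates 2 and 3. HMGA1 lost its call without any of 8 arrays (adjusted p = 0.0502 to 0.129): all MMS1 controls, MMS1 miR-16 sponge replicates 2 and 3, RPMI8226 control sponge replicates 2 and 3 and RPMI8226 miR-16 sponge replicate 2. With replicate number as a block, UNG gave an adjusted p = 0.052 and HMGA1 gave 0.0725. With the mean over its probe sets ETS1 gave -0.14 (adjusted p = 0.465) and CCND2 gave -0.24 (adjusted p = 0.113). CCND3 passed as lower in MMS1 with quantile normalization (adjusted p = 0.0423) and among the brighter probe sets (adjusted p = 0.0325). Calls in the average were fragile too. There CDC25A lost its call without any of 8 arrays, VEGFA of 6, IKBKB of 4 and HMGA1 of 1 (adjusted p = 0.0501 to 0.0655). With the block, CDC25A gave 0.0638, VEGFA 0.072 and HMGA1 0.0513. With the mean over probe sets, PURA gave 0.221 and ETS1 0.164.

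**Figure D2:**
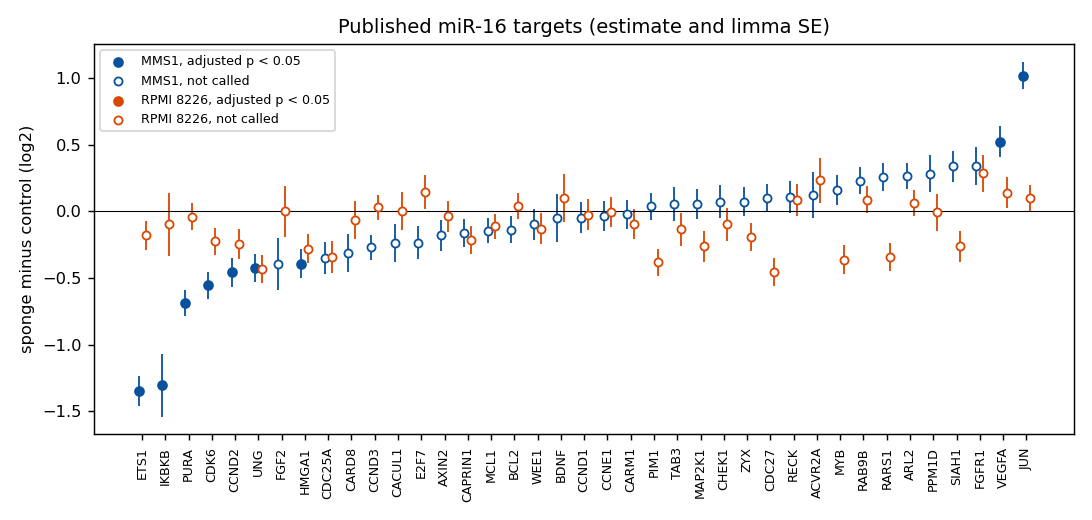
Log2 change from control sponge to miR-16 sponge of published miR-16 targets in MMS1 and RPMI8226, as points with standard errors from limma. BCL2 lay at -0.14 and 0.04, and JUN at 1.02 in MMS1.

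With the miR-16 sponge, both lines gained signal for the adult globin genes HBB and HBD, which encode the beta and delta chains of hemoglobin. In RPMI8226, HBB rose from 10.55 ± 0.05 to 13.71 ± 0.04 (SD, n = 3 each), or 8.95-fold (adjusted p = 2.84e-09). In MMS1 it rose from 8.76 ± 0.16 to 11.67 ± 0.03, or 7.50-fold (adjusted p = 1.06e-09). HBD rose 3.76-fold in RPMI8226 (adjusted p = 3.34e-07) and 2.62-fold in MMS1 (adjusted p = 5.61e-07). The HBB change did not differ between lines by limma's interaction test (difference 0.26, adjusted p = 0.375), and the HBD change was larger in RPMI8226 (difference 0.52, adjusted p = 0.0362). The HBD difference no longer passed without any of 11 arrays, all except MMS1 miR-16 sponge replicate 1 (adjusted p = 0.0579 to 0.0951), nor with replicate number as a block (adjusted p = 0.115). Of 4 HBB probe sets, 3 rose in both lines, and the remaining 1 gave -0.12 and 0.05. The 3 that rose are all of the x_at kind, so they do not exclude signal from related globin transcripts. HBD had 1 probe set. HBE1 gave -0.21 in MMS1 (adjusted p = 0.161) and -0.49 in RPMI8226 (adjusted p = 0.046). The RPMI8226 call was lost without any of 11 arrays, all except MMS1 miR-16 sponge replicate 1 (adjusted p = 0.0545 to 0.163), and with replicate number as a block (adjusted p = 0.227). The mean over both probe sets gave -0.17 (adjusted p = 0.335). The main HBE1 probe set, at 14.39 in the MMS1 controls, lay close to the highest value of 14.71, so the full size of a rise could not have been seen. HBZ fell by 1.94 in MMS1 (adjusted p = 2.04e-08) and gave -0.01 in RPMI8226.

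The 22 other erythroid genes did not follow HBB and HBD in MMS1, where 3 of them rose and 12 fell by limma's test. In RPMI8226 only 3 of all genes passed as higher. Among the 22, 0 rose and 1 fell, and 11 estimates were positive and 11 negative, with a median of 0.017. In the simulated data 79.1% of changes of 1 and 100% of changes of 2 were called in that comparison, so smaller rises could have been missed. In MMS1 the red cell membrane gene RHAG rose by 2.47 (adjusted p = 2.04e-08) and the carbonic anhydrase gene CA2 by 2.06. The heme synthesis gene ALAS2 fell by 2.51 (adjusted p = 1.15e-07), CA1 fell by 2.51, ERMAP fell by 1.91 and KLF1 fell by 1.85 (adjusted p = 1.97e-07). GATA1 fell by 0.41 (adjusted p = 0.0158), but gave 0.0566 and 0.0742 without MMS1 control sponge replicates 1 and 3 and 0.0557 without MMS1 miR-16 sponge replicate 3, and 0.0726 with replicate number as a block. Over all 24 erythroid genes in MMS1, 5 rose and 12 fell, or 5 and 14 adjusted over the list alone, with a median of -0.39 (camera, adjusted p = 0.00977). The call ended with an estimated correlation (adjusted p = 0.217). In RPMI8226, 2 rose and 1 fell, or 2 and 5 adjusted over the list alone (camera, adjusted p = 0.451). The erythroid list differed between lines (median difference 0.49, adjusted p = 0.000264), but not with an estimated correlation (adjusted p = 0.187). This list was chosen on these arrays, so neither count is independent evidence.

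**Figure D3:**
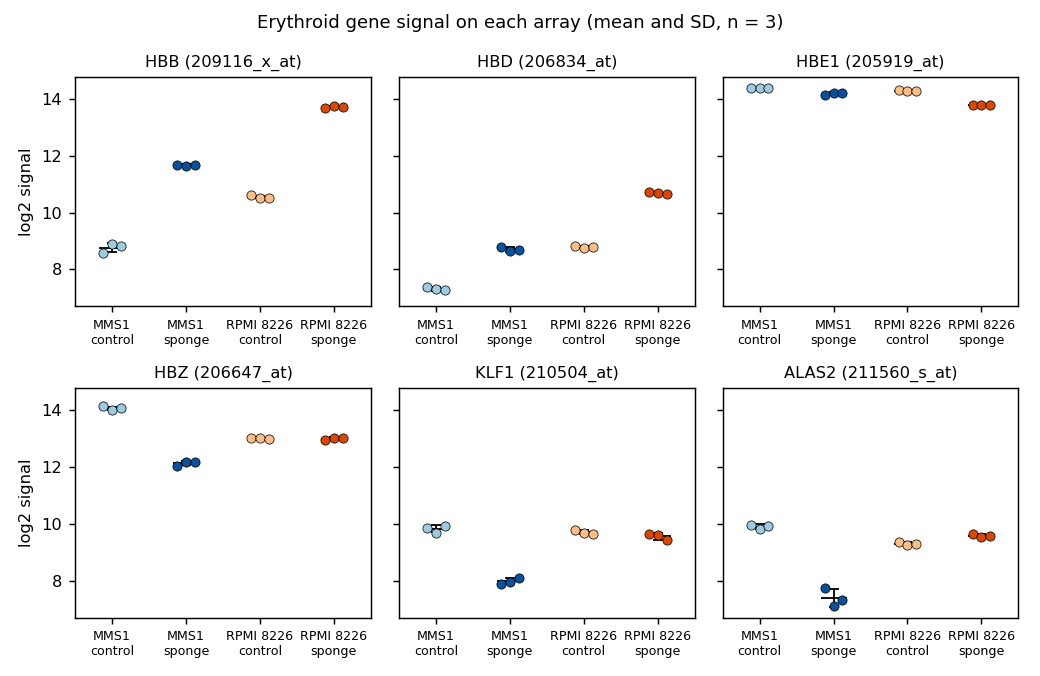
Log2 signal of erythroid genes on each array (points), with the mean and SD of 3 arrays per group. HBB rose from 8.76 to 11.67 in MMS1 and from 10.55 to 13.71 in RPMI8226, while HBZ fell by 1.94 in MMS1 and gave -0.01 in RPMI8226.

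In the arrays labelled MMS1, the miR-16 sponge went with large changes in single genes. KCNC2, a voltage-gated potassium channel gene, rose from 4.41 ± 0.10 to 10.18 ± 0.04 (SD, n = 3 each, adjusted p = 2.44e-11), a log2 change of 5.77 with a standard error of 0.128. Its controls lay near the lower bound of 4, so the true change may be larger. CD3D, which encodes a chain of the T cell receptor complex, rose from 6.77 ± 0.11 to 12.41 ± 0.15 (change 5.64, adjusted p = 2.44e-11). The mucin gene MUC19 rose by 4.58 and the inflammasome-related gene NLRP7 by 4.49. SOSTDC1, an inhibitor of BMP and WNT signals, rose by at least 4.53, since its control arrays lay at the lower bound. PRG2, the eosinophil major basic protein gene, rose by 3.97, CSDC2 by 3.93 from controls near that bound, and ANXA1, a calcium-dependent phospholipid-binding protein gene, by 3.85. EXOC6B, an exocyst subunit gene, fell from 10.38 ± 0.02 to 5.56 ± 0.50 (change -4.82, adjusted p = 1.07e-08). The imprinted noncoding RNA gene MEG3 fell from 10.45 ± 0.28 to 5.89 ± 0.18 (change -4.57, adjusted p = 1.06e-09). Of 10 MEG3 probe sets, 5 fell and the rest did not pass. The germ cell gene TEX19 fell by 4.13 and the Notch glycosyltransferase gene MFNG fell by 3.84. The adaptor gene FYB1 fell by 2.98 and the small GTPase gene RAP1A fell by 2.89. The phospholipase gene PLA2G2A fell by 2.76, and KIR2DS5 fell by 2.84, from a family of such similar genes that the member is uncertain. For each gene named here, the 3 sponge arrays lay all above or all below the 3 control arrays.

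Several gene lists passed camera's test in MMS1, with every called member moving the same way. Of 29 DNA replication genes, 0 rose and 15 fell, or 0 and 21 adjusted over the list alone, with a median change of -0.37 (camera, adjusted p = 6.6e-10). The thymidine kinase gene TK1 fell by 0.97 (adjusted p = 1.59e-05), and the replication helicase genes CDC45 and MCM6 fell by 0.95 each and MCM10 fell by 0.83. Of 30 mitosis genes 9 fell and 0 rose, or 13 and 0 adjusted over the list alone (median -0.22, adjusted p = 0.000246). Among them ASPM changed by -0.70, the kinase gene AURKA by -0.65, BUB1 by -0.58 and CDC25C by -0.52. Of 24 genes of the unfolded protein response, 6 rose and 0 fell, or 8 and 0 adjusted over the list alone (median 0.20, adjusted p = 9.89e-05). HSPA5, the main chaperone of the endoplasmic reticulum, rose by 1.20 (adjusted p = 1.62e-05), the stress transcription factor gene DDIT3 by 0.67, HSP90B1 by 0.66 and PDIA4 by 0.50. Of 26 interferon response genes, 7 fell and 0 rose, or 9 and 0 adjusted over the list alone (median -0.23, adjusted p = 0.00163). USP18 changed by -1.06, OAS3 by -1.05, ISG15 by -0.91 and IFIH1 by -0.68. Of 10 epithelial markers, 5 rose and 0 fell, also when adjusted over the list alone (median 0.30, adjusted p = 0.00018). The keratin gene KRT8 rose by 2.60 (adjusted p = 1.77e-09), KRT18 by 1.11, ELF3 by 0.70 and EPCAM by 0.60. ELF3 gave an adjusted p = 0.06 with the mean over its probe sets. With an estimated correlation between genes, the replication and unfolded protein response lists gave an adjusted p = 0.406, the mitosis list 0.645, and the interferon and epithelial lists 0.256, so 0 of these calls held.

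Calls for 2 metabolic lists in MMS1 were less firm. Of 25 hypoxia and glycolysis genes, 6 rose and 4 fell, or 9 and 4 adjusted over the list alone (median 0.10, camera adjusted p = 0.0445). The mitophagy gene BNIP3 rose by 0.73 and the glucose transporter gene SLC2A3 by 0.45, while the glucose transporter gene SLC2A1 fell by 0.59 and NDRG1 fell by 0.50. SLC2A1 gave an adjusted p = 0.0892 with the mean over its probe sets. The list's adjusted p was 0.173 with quantile normalization, 0.057 with replicate number as a block, 0.0942 with fry and 0.645 with an estimated correlation. It was 0.135 without MMS1 control sponge replicate 2, 0.0947 without MMS1 miR-16 sponge replicate 1, 0.0525 and 0.0516 without RPMI8226 control sponge replicates 1 and 3, and 0.0541 and 0.0501 without RPMI8226 miR-16 sponge replicates 2 and 3. Of 29 genes of the mitochondrial respiratory chain, 3 rose and 2 fell, or 4 and 3 adjusted over the list alone (median 0.14, adjusted p = 0.0218). The complex I genes NDUFV1 and NDUFV2 rose by 0.49 each and UQCRC1 by 0.36, and SDHA fell by 0.32. NDUFV1 gave an adjusted p = 0.202 with the mean over its probe sets. UQCRC1 lost its call without any of 4 arrays, MMS1 control sponge replicates 2 and 3 and MMS1 miR-16 sponge replicates 2 and 3 (adjusted p = 0.0672 to 0.127). SDHA lost its call without any of 11 arrays, all except MMS1 miR-16 sponge replicate 1 (adjusted p = 0.0581 to 0.139). With replicate number as a block, UQCRC1 gave 0.0886 and SDHA gave 0.138, and UQCRC1 gave 0.0609 with quantile normalization. The list's value was 0.308 with quantile normalization, 0.111 without MMS1 control sponge replicate 2 and 0.645 with an estimated correlation. The other 22 lists did not pass in MMS1, although single members did. CD24, a surface glycoprotein gene on the B cell list, rose by 2.79 (adjusted p = 1.06e-09), and the chemokine gene CXCL8 rose by 2.24.

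In all, 5635 probe sets passed limma's test in MMS1, of which 2296 were higher and 3339 lower with the sponge. By gene, 858 rose and 1597 fell among 19775. A log2 change of at least 1 was found for 734 probe sets. Without MMS1 miR-16 sponge replicate 1, the array with low ribosomal RNA signal, 5570 passed. The count was 3730 without MMS1 control sponge replicate 3 and 3739 without MMS1 control sponge replicate 1.

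In the arrays labelled RPMI8226, fewer genes passed limma's test, and 40 of 43 fell in the fit to all arrays. Besides HBB and HBD, only TEX19 rose, from 8.26 ± 0.04 to 10.01 ± 0.10 (SD, n = 3 each; change 1.75, adjusted p = 1.18e-06). The aldo-keto reductase gene AKR1C3 fell from 7.31 ± 0.11 to 6.17 ± 0.15 (change -1.14, adjusted p = 0.00136), and the noncoding RNA gene FILNC1 fell by 1.21 (adjusted p = 0.00238). The calcium-binding protein gene CALB1 fell by 1.07 (adjusted p = 0.00238). CFLAR, which encodes an inhibitor of caspase 8, fell by 1.02 (adjusted p = 0.0015), but only 3 of its 14 probe sets fell and their mean gave -0.29 (adjusted p = 0.122). The medium-chain acyl-CoA synthetase gene ACSM3 fell by 0.90 (adjusted p = 0.00136). The growth-response transcription factor gene EGR1 fell by 0.91 (adjusted p = 0.0135), in 1 of 3 probe sets. It gave 0.065 without RPMI8226 control sponge replicate 1, and 0.0735 and 0.0849 without miR-16 sponge replicates 1 and 2 of that line. The caveolar protein gene CAVIN2 fell by 0.90 (adjusted p = 0.0343). It lost its call without any of 9 arrays, all except the MMS1 miR-16 sponge arrays (adjusted p = 0.0604 to 0.147). PLCL1 fell by 0.89 (adjusted p = 0.00874), and gave 0.055 and 0.0695 without RPMI8226 control sponge replicates 2 and 3 and 0.0562 without miR-16 sponge replicate 2. With replicate number as a block, ACSM3 gave an adjusted p = 0.0519, CFLAR 0.0587, EGR1 and PLCL1 0.0999 and CAVIN2 0.148.

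Gene lists that passed in RPMI8226 were all lower with the sponge, mostly through small changes in genes that did not pass singly. Of 20 MYC and ribosome biogenesis genes, 0 passed over all probe sets, and 0 rose and 12 fell adjusted over the list alone (median -0.27, camera adjusted p = 8.57e-07). MYC itself, which drives growth, gave -0.47 (adjusted p = 0.0643), and the nucleolar protein gene NPM1 gave -0.37 (adjusted p = 0.114). Of 14 heat shock and chaperone genes, 0 passed over all and 4 fell adjusted over the list alone (median -0.20, adjusted p = 0.000318), with HSPE1 at -0.47 (adjusted p = 0.0872). Of 17 cholesterol synthesis genes, 1 fell and 0 rose over all, and 6 fell adjusted over the list alone (median -0.18, adjusted p = 0.00698). That gene was SQLE, which encodes squalene epoxidase and fell by 0.60 (adjusted p = 0.0468). SQLE lost its call without any of 10 arrays, all except MMS1 miR-16 sponge replicates 1 and 3 (adjusted p = 0.0649 to 0.162), with replicate number as a block (adjusted p = 0.205) and with the mean over its probe sets (adjusted p = 0.0564). With an estimated correlation these 3 lists gave an adjusted p = 0.494. Of 30 mitosis genes, 0 passed over all and 1 fell adjusted over the list alone (median -0.15, adjusted p = 0.000983), with ASPM at -0.59 (adjusted p = 0.0686). The mitosis value was 0.0594 with quantile normalization, 0.0885 with fry and 0.597 with an estimated correlation. Of 29 respiratory chain genes, 0 passed over all and 3 fell adjusted over the list alone (median -0.09, adjusted p = 0.00698), with ATP5F1A at -0.40 (adjusted p = 0.111). Among 25 hypoxia and glycolysis genes 1 fell, NDRG1, with a change of -0.64 (adjusted p = 0.027), and 4 fell adjusted over the list alone (median -0.07, adjusted p = 0.0273). With quantile normalization the respiratory chain and hypoxia lists each gave 0.146, and with an estimated correlation 0.597. The respiratory chain value was also 0.0838 with the mean over probe sets and 0.05 among the brighter probe sets. NDRG1 lost its call without any of 9 arrays, all except the MMS1 miR-16 sponge arrays (adjusted p = 0.0503 to 0.124), and with replicate number as a block (adjusted p = 0.18). Without MMS1 miR-16 sponge replicate 1, MYC, NPM1, HSPE1 and ASPM passed as lower (adjusted p = 0.0291, 0.0497, 0.0366 and 0.0261). Among the brighter probe sets these 4 and ATP5F1A passed (adjusted p = 0.0105, 0.0263, 0.0182, 0.013 and 0.026), and with the mean over probe sets MYC, NPM1 and HSPE1 did (adjusted p = 0.0227, 0.044 and 0.0445). The hypoxia value was 0.0545 with replicate number as a block, 0.0665 with fry and 0.0678 among the brighter probe sets. It was 0.0623 without RPMI8226 control sponge replicate 2, and 0.0704 and 0.0934 without miR-16 sponge replicates 2 and 3 of that line. The other 23 lists did not pass.

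Over all probe sets, 107 passed limma's test in RPMI8226, 13 higher and 94 lower. At an unadjusted p under 0.05 there were 7459, against 12261 in MMS1, so the lines lay closer there than in their calls. The count of 107 moved with the arrays and the fit. It was 723 without MMS1 miR-16 sponge replicate 1, whose spread enters the common variance, and 105 and 78 without MMS1 miR-16 sponge replicates 3 and 2. Without the MMS1 control sponge arrays it was 30, 36 and 35 for replicates 1 to 3, without the RPMI8226 control sponge arrays 24, 27 and 22, and without the RPMI8226 miR-16 sponge arrays 30, 31 and 36. A variance trend with signal gave 1697 and replicate number as a block gave 11. The balance toward falls depended on the fit as well: with the block 7 were higher and 4 lower, and with the arrays of that line alone 6 were higher and 2 lower.

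**Figure D4:**
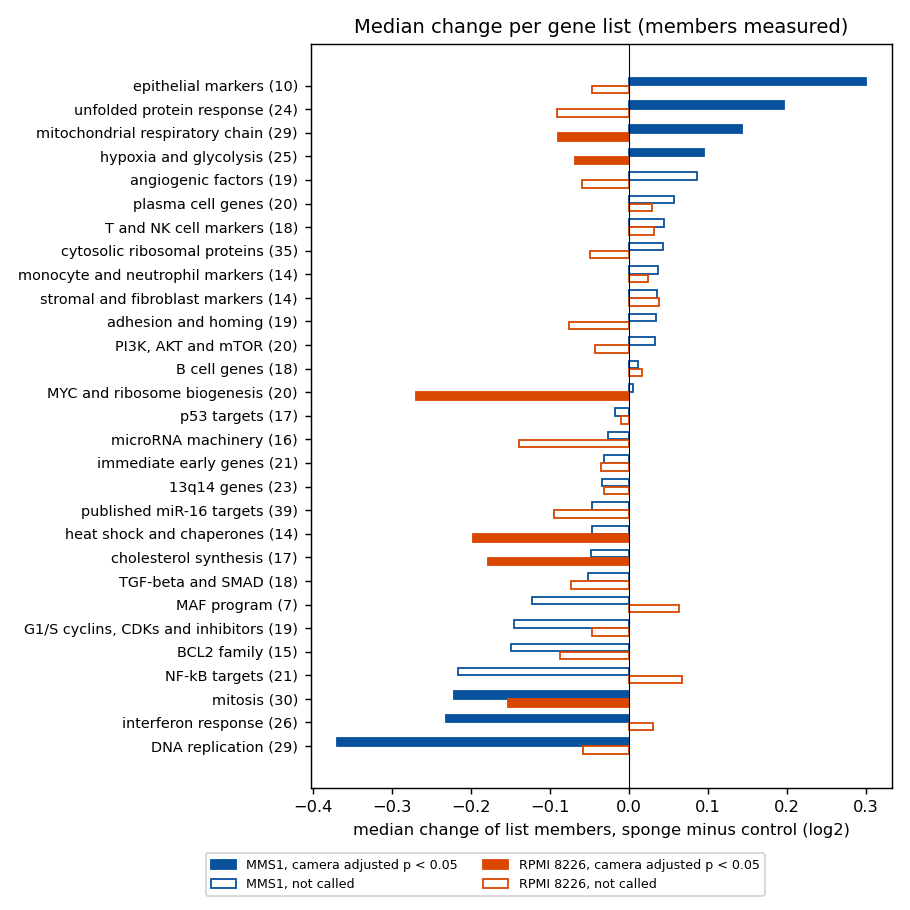
Median log2 change of the measured members of each gene list (number in brackets) in MMS1 and RPMI8226, with filled bars for camera adjusted p under 0.05. DNA replication had a median of -0.37 in MMS1, and MYC and ribosome biogenesis of -0.27 in RPMI8226.

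Whether the sponge acted alike in both lines was asked from the overlap and the average. Higher in both lines were 2 genes, HBB and HBD, where 0.13 were expected from independent calls (Fisher's exact test, p = 0.00548). Lower in both were 11 genes, where 3.23 were expected (Fisher's exact test, p = 0.000237). These were ACSM3, FILNC1, EGR1, DAB2, CAVIN2, RNFT2, GASK1B, CFLAR, PTPRR, NDRG1 and ST6GAL1. Opposite directions were found for 10 genes, against 1.98 expected, among them TEX19, CALB1, ANXA1, CXCL8 and SQLE. The calls of both lines share each probe set's spread from 1 fit, so they are not independent. Opposite directions exceeded their expected count too, so the Fisher tests do not show that the sponge acted alike in both lines. The overlap names were taken as they fell. Across 19775 genes the changes in both lines had a Pearson correlation of 0.0544 and a Spearman correlation of 0.0658. Genes are not independent replicates. The 13 genes shared in direction became 75 without MMS1 miR-16 sponge replicate 1, and 12 and 13 without replicates 2 and 3 of that group. They became 7, 8 and 8 without MMS1 control sponge replicates 1 to 3, 6, 7 and 7 without RPMI8226 control sponge replicates 1 to 3, and 6, 7 and 8 without RPMI8226 miR-16 sponge replicates 1 to 3.

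**Figure D5:**
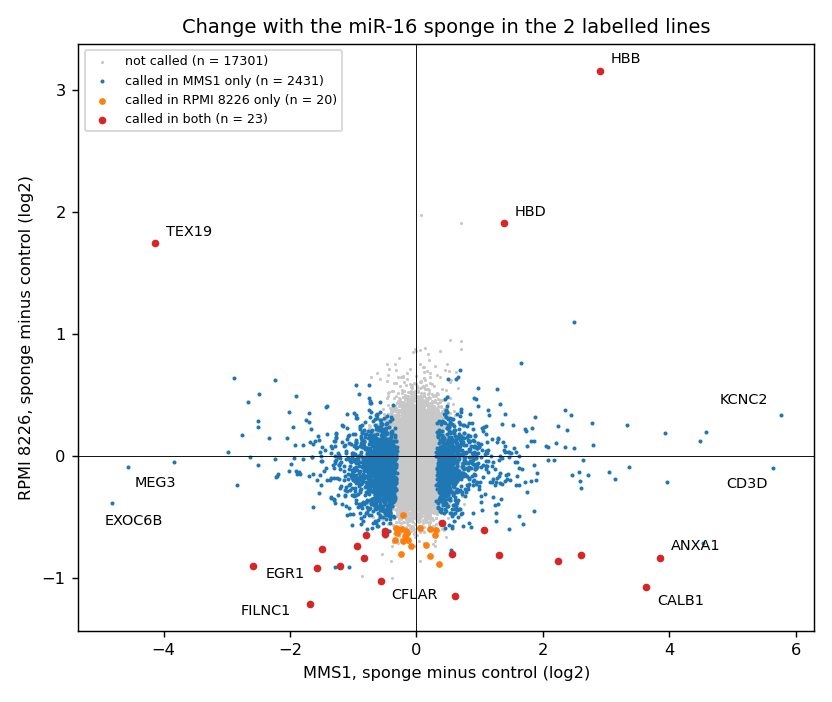
Log2 change with the miR-16 sponge in MMS1 (horizontal) against RPMI8226 (vertical), 1 point per gene. HBB lay at 2.91 and 3.16 and TEX19 at -4.13 and 1.75.

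Averaged over both lines, HBB rose by 3.03 (adjusted p = 3.65e-11) and ACSM3 fell by 1.74 (adjusted p = 4.58e-09). Other large averages rested mostly on MMS1, such as KCNC2 at 3.05, MUC19 at 2.39, NLRP7 at 2.31 and CSDC2 at 2.06, and, falling, EXOC6B at -2.60, MEG3 at -2.33, MFNG at -1.94 and KIR2DS5 at -1.54. ZNF491 rose by 1.79 and FILNC1 fell by 1.45, each with 1 MMS1 group at the lower bound, so these are lower limits of the size. In the average, 3929 probe sets passed, 1156 higher and 2773 lower. The count was 2574 without MMS1 control sponge replicate 3. By list, 13 of 29 DNA replication genes fell (median -0.25, camera adjusted p = 7.58e-09) and 9 of 30 mitosis genes (median -0.18, adjusted p = 5.32e-06). The unfolded protein response list was higher, with 2 of 24 genes up (median 0.08, adjusted p = 0.00471), as was the epithelial list, with 3 of 10 up (median 0.15, adjusted p = 0.000225). Except for mitosis, which passed in both lines, these averages also rested on MMS1: in RPMI8226 the medians were -0.09 for the unfolded protein response, -0.05 for epithelial markers and -0.06 for DNA replication (camera, adjusted p = 0.646, 0.976 and 0.36). Of 18 T and NK cell markers 2 rose, CD3D and CD7 (median 0.08, adjusted p = 0.0229, and 0.0704 with quantile normalization). That value was 0.0638 without MMS1 miR-16 sponge replicate 3 and 0.0855 without RPMI8226 miR-16 sponge replicate 1. Of 14 heat shock genes 2 fell (median -0.12, adjusted p = 0.0133, and 0.0641 among the brighter probe sets). With an estimated correlation the epithelial list gave an adjusted p = 0.501 and the other 5 gave 0.55.

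The change from control to sponge differed between the lines at many genes, by a test of the difference itself. As far as the labels say, each sponge and line was 1 sorted population. Differences between populations therefore cannot be told apart here from differences in the response to the sponge. TEX19 differed most among positive differences, falling in MMS1 and rising in RPMI8226 (difference 5.88, adjusted p = 4.88e-11). The difference was 4.48 for MEG3, 4.43 for EXOC6B, 3.80 for MFNG and 3.53 for RAP1A, all of which fell in MMS1. It was -5.74 for CD3D, -5.43 for KCNC2, -5.24 for SOSTDC1, -4.71 for CALB1 and -4.68 for ANXA1, all of which rose in MMS1. For SOSTDC1 the size is a lower limit, since its MMS1 controls lay at the lower bound, and those of KCNC2 lay near it. In RPMI8226, CALB1 fell by 1.07 and ANXA1 fell by 0.83. ANXA1 lost its RPMI8226 call without any of 5 arrays, the RPMI8226 controls and miR-16 sponge replicates 1 and 3 (adjusted p = 0.0546 to 0.0695), and with replicate number as a block (adjusted p = 0.145). In all, 2786 probe sets passed limma's interaction test, 1094 with a positive and 1692 with a negative difference. The count was 1845 without RPMI8226 miR-16 sponge replicate 2 and 1854 without RPMI8226 control sponge replicate 3.

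The control-sponge arrays of the lines, compared with each other, show the background on which the sponge acted. MEG3 was lower in RPMI8226 controls than in MMS1 controls by a log2 difference of -4.81, ID2 by -2.81 and CA1 by -2.70. ANXA1 was higher by 3.37, RHAG by 3.10, the fibronectin gene FN1 by 2.85, KRT8 by 2.40 and HBB by 1.78. These genes were chosen after their values were seen. In this comparison 4465 probe sets passed limma's test, 2974 of them higher in RPMI8226. The count was 2747 without MMS1 control sponge replicate 1, 2915 without MMS1 control sponge replicate 2, and 2826 and 2788 without RPMI8226 control sponge replicates 2 and 3.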

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

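The tests on cell identity and on the globin genes were chosen only after the results were seen, and those on the MMS1 array, on neighbouring genes and on other splits of the arrays before. Differences between the lines in their change from control to miR-16 sponge are listed first, since a test of the difference itself singled them out. By limma's interaction test, this change differed between RPMI8226 and MMS1 for 2786 probe sets, which may also reflect differences between the sorted populations. Expressed as RPMI8226 effect minus MMS1 effect on the log2 scale, the difference was 5.88 for TEX19, 4.48 for MEG3, 4.43 for EXOC6B, 3.80 for MFNG and 3.53 for RAP1A. It was -5.74 for CD3D, -5.43 for KCNC2, -5.24 for SOSTDC1, -4.71 for CALB1 and -4.68 for ANXA1. The size for SOSTDC1 is a lower limit, since its MMS1 controls lay at the lower bound, and those of KCNC2 lay near it. Among gene lists, the median difference was 0.28 for DNA replication (camera, adjusted p = 3.16e-06) and 0.28 for interferon response (adjusted p = 0.000525). It was -0.31 for the unfolded protein response (adjusted p = 0.000432), -0.23 for epithelial markers (adjusted p = 0.00107), -0.28 for hypoxia and glycolysis and -0.21 for MYC and ribosome biogenesis (adjusted p = 0.000525 each). The respiratory chain list gave -0.17 (adjusted p = 0.000432), and cholesterol synthesis and adhesion and homing gave -0.11 and -0.10 (adjusted p = 0.0469 each). With an estimated correlation between genes 0 of these 9 lists passed (adjusted p from 0.362 to 0.459).

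The first pattern is that plasma cell and immunoglobulin genes had medians near or below the middle of all genes on all 12 arrays, while erythroid genes stood high. Failed arrays or shifted probe annotation would scatter genes of every kind, and the lowest array still had ribosomal protein genes at percentile 99.8. Erythroid RNA added to a majority of plasma cell RNA would leave immunoglobulin transcripts, the most abundant of plasma cells, far up. It is argued against, since the highest of 117 immunoglobulin probe sets on any array reached 7.49, below the upper quartile of genes at 7.62; cells that made no immunoglobulin would escape this test. The RNA may have come from erythroid cells rather than from the myeloma lines of the labels: the 18 erythroid genes not among those first noticed had a higher median percentile than the plasma cell genes on 12 of 12 arrays, at 60.7 to 83.7, where 0.35% of 10000 random lists lay higher. This is a hypothesis from the same arrays, it names no other line, sorting for GFP would not have removed such cells, and how many erythroid genes these myeloma lines normally express was not tested.

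The second pattern is the rise of HBB and HBD with the miR-16 sponge in both lines. A rise of erythroid genes as a group is argued against in MMS1, since 12 of the 22 other erythroid genes fell there. In RPMI8226, 11 of the 22 had a positive and 11 a negative change, called or not, with a median of 0.017. That count lay between the bounds set for and against a rise of the group, so the test cannot decide. HBB rose by 3.16 and HBD by 1.91 in RPMI8226, amounts that the median of the 22 did not reach. A smaller rise of some members stays open. Signal from HBZ transcripts on the HBB probe sets is argued against, since the higher of the HBZ changes in the lines was -0.014. For signal from HBE1 the test cannot decide, since it asked for at least 1 log2 unit of room below the highest value. Its main probe set went from 14.39 to 14.18 in MMS1 and from 14.28 to 13.80 in RPMI8226, so the higher of its changes was -0.208. That probe set lay too close to the highest value on the arrays for a rise to be judged. The RPMI8226 call was fragile, and the other HBE1 probe set gave 0.05 and 0.15, neither called. Gamma globin transcripts were not analysed singly, so signal from globin transcripts other than HBZ stays open. Globin sequence carried by the sponge vector could raise HBB alike in both lines, and the lines differed by 0.255, which an effect of the sponge on the gene would also allow, so these cannot be told apart without the vector sequence. Since each sponge and line was 1 sorted population as far as the labels say, a difference between populations that was present before the sponge stays open too.

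The third pattern is that MMS1 had many more calls than RPMI8226. At an unadjusted p under 0.05 by limma's test the counts lay closer, at 12261 and 7459. The number of calls alone therefore does not measure how many genes changed. A single array with low ribosomal RNA signal is argued against as the whole cause, since 5570 probe sets still passed in MMS1 without it. It carried part of the gap, since without it RPMI8226 rose from 107 to 723 calls. With a variance trend the counts were 7154 and 1697, so both rose and only their ratio fell clearly. The MMS1 populations may differ in copy number over chromosome regions: a gene's change correlated with the median change of its 10 neighbours on each side at 0.161 by rank across 13025 genes, against a highest value of 0.041 in 1000 shuffled gene orders. In RPMI8226 the correlation was 0.06, lower than in MMS1 but also above its highest shuffled value of 0.028 in 200 orders. Genes are not independent replicates, and neighbours regulated together or a bias with base composition would give such a correlation as well. The MMS1 controls correlated with the RPMI8226 controls at 0.968 to 0.971 and with the MMS1 sponge arrays at 0.960 to 0.969. Of the genes called in MMS1 with a log2 change of at least 2, the RPMI8226 controls lay nearer the MMS1 sponge arrays than the MMS1 controls for 19 of 36 that rose and 16 of 24 that fell. A true difference between the lines in their dependence on miR-16 was not tested and stays open.

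For each comparison, other splits of the same arrays were fitted. With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. In MMS1, 1 of 10 gave as many as the real 5635 calls, and the highest other gave 1. In RPMI8226, 1 of 10 gave as many as 107, and the highest other gave 0, as did the highest other for the 4465 calls between the controls, where again 1 of 10 gave as many. For the average, 1 of 100 splits drawn from 200 gave as many as 3929 calls, with 2068 as the highest other drawn. For the difference, 1 of 100 gave as many as 2786, with 1818 as the highest other drawn. Those high values came from splits that kept the real MMS1 groups, 14 of those drawn. With any other MMS1 split the highest were 1 and 1. Swapping sponge and control in RPMI8226 alone exchanges average and difference, so that split, not drawn, would give 3929 for the difference. The splits do not exclude chance, since the arrays of a group may come from 1 cell population.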

How the results depend on the processing

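All alternatives reported here were fixed before the tests were run, and no single gene or list changed direction while called. Of 159 results for single genes, leaving out 1 array left 1787 fits on the same side of the threshold, moved 114 off it and 7 onto it. Quantile normalization kept 156, moved 1 off and 2 on. The mean over probe sets kept 146, moved 10 off and 3 on, and the brighter probe sets alone kept 144 and moved 11 on. Of 22 list results, an estimated correlation moved 19 below the threshold, fry 3, quantile normalization 6, the brighter probe sets 3 and the mean over probe sets 1, and leaving out 1 array moved 12 fits off it and 2 onto it.

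Counts of called probe sets moved most in RPMI8226, where 107 were called. Median centring gave 164, a variance trend 1697, the trend with robust estimation 1766, the brighter probe sets alone 1268, array weights 524 and the arrays of that line alone 8. Of the 107, 13 were higher and 94 lower, against 6 and 2 with that line alone and 7 and 4 with the block. For the difference between lines, the trend gave 4577, with robust estimation 4649, and the brighter probe sets 4267. In MMS1, that line alone gave 3735. The trend and the smaller set of probe sets change the variance prior and the number of tests, and beyond that the cause was not tested. A log2 change of at least 1 left 734 in MMS1, 19 in RPMI8226, 146 in the average, 902 in the difference and 579 between controls. An adjusted p under 0.01 left 2905, 23, 1639, 1097 and 2235. The 13 genes shared by the lines became 22 with centring, 202 with the trend, 197 with robust estimation, 152 among the brighter probe sets and 58 with array weights.

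With the replicate number as a block, which the pairing check did not call for, MMS1 gave 3859 calls, RPMI8226 gave 11, the average 2139, the difference 1376 and the controls 2860, and 3 genes were shared. The block takes up degrees of freedom; the remaining cause was not tested. It kept 141 single-gene results, moved 18 off the threshold and moved 2 list results off it.

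Without 1 array at a time, calls ranged from 3730 to 5570 in MMS1, 22 to 723 in RPMI8226, 2574 to 5159 in the average, 1845 to 2797 in the difference and 2747 to 5379 between controls, and shared genes from 6 to 75. The 7 lists called in MMS1 ranged from 5 to 8, the 6 in RPMI8226 from 5 to 7 and the 6 in the average from 5 to 8. An estimated correlation gave 0 lists in each. Fry gave 14 in MMS1 and 15 in the average, and quantile normalization gave 3 in RPMI8226.

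Scaling moved the share of higher calls. Of 4465 calls between controls 2974 were higher in RPMI8226, against 2734 of 4930 with quantile normalization and 2485 of 4450 with centring; in the average 1156 of 3929 were higher, against 1755 of 4251 with quantile normalization. Alternative pseudocounts and the search for seed sites were not run, the first because values were already log2. Signals near the lower bound of 4 limit the fold of dim genes.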

Other observations

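Fibronectin and other genes outside the comparisons' named sets also changed in MMS1. FN1 rose by 1.55, the cell-surface gene CD47 by 0.65 and the integrin gene ITGA4 by at least 1.13, since 2 of its 3 control arrays lay at the lower bound. On the B cell list the transcription factor gene BACH2 fell by 1.24, and among NF-kB targets the cytokine gene EBI3 fell by 1.68, with 1 sponge array near the lower bound. Among cell cycle regulators CDK4 fell by 0.74 and the inhibitor gene CDKN1A rose by 0.60. The pro-apoptotic gene PMAIP1 rose by 0.84, the vascular receptor gene FLT1 fell by 1.54 and the small heat shock gene HSPB1 fell by 1.14. The inhibitor of differentiation ID2 fell by 1.23, the mTOR partner gene RPTOR fell by 1.02 and the RNA helicase gene MOV10 fell by 0.89. These genes belong to lists that did not pass as lists in MMS1, and were chosen after their values had been seen. Of 23 genes at 13q14, FNDC3A rose by 0.90 and the rest did not pass (camera, adjusted p = 0.553). Of 35 cytosolic ribosomal protein genes 0 passed in either line by limma's test (camera, adjusted p = 0.363 in MMS1 and 0.332 in RPMI8226).

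The neighbour correlation was also computed between the control-sponge arrays of the lines. It was 0.146 across 13025 genes, against a highest value of 0.033 in 200 shuffled gene orders.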
